A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

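RNA-seq was done on 4 mouse livers and on 4 samples of Huh7, an established human hepatoma line, with 1 library each. The livers came from a wild-type mouse on normal chow (ND), a wild-type mouse on a diet abbreviated HFHC in the labels, and a wild-type and a Gpnmb knockout mouse on a diet abbreviated AMLN. The labels give 4 months for the ND and HFHC livers and 3 months for the AMLN livers, without saying whether this is age or time on the diet. Per the labels, the Huh7 cells carried transfected RYK, a receptor of the WNT system. No untransfected cells were analysed here, so whether each library overexpresses it was not tested. The cells received the extracellular domain (ECD) of GPNMB or vehicle for 8 hours. The labels number the Huh7 libraries 1 and 2 in each treatment, with RYK1 and RYK2 in the titles. Groups were taken from these labels, with n = 1 in each mouse group and n = 2 in each Huh7 group.

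Per the labels' protocols, RNA was extracted with an RNAprep pure kit and mRNA libraries were made for DNBSEQ sequencing. Per the submitters' processing notes, the builds were GRCm38 for mouse and GRCh38 for human. The aligner, the counter and their versions are not given in the sources used here. Per the file headers, the authors deposited FPKM values (fragment counts scaled by gene length and library depth), rounded to 2 decimals, in 4 tables of 2 libraries each. The tables also hold the authors' log2 fold change, p-value and false discovery rate for the 2 libraries in each, from a Poisson test named in the file headers. Those deposited p-values compare 2 libraries, not 2 conditions. They were used only to estimate depth and where the authors' deposited table is named. In the mouse tables the authors' deposited log2 fold change equals the log2 ratio of the FPKM columns with 0 replaced by 0.01. The authors' deposited false discovery rate reached 1.03 in the AMLN table and was treated as a score with no fixed range. No column of per-sample values was left unmapped. A single line of the AMLN table and 92 lines of each Huh7 table were not used here, so some genes and members of lists are missing from the counts.

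Depth per library was not given, so it was estimated from the authors' deposited p-values for genes listed at 0 in 1 library of a table. Among genes listed at 0 in 1 library of a table, the relative depth was 0.959 for HFHC over ND, 1.00 for knockout over wild type, 1.17 for ECD over vehicle in number 1 and 1.05 in number 2. Each p-value was turned into reads by taking it to fall by a fixed factor with every read. Between 97.6% and 99.5% of the results lay within 0.05 reads of a whole read. With transcript lengths from the GENCODE mouse annotation, the median estimate was 23.6 M fragments for HFHC, 22.2 M for ND (from 6 genes), 16.2 M for the knockout and 15.8 M for AMLN wild type (M, 1e6). A gene of 2 kb at an FPKM of 1 then stands for about 47.2, 44.4, 32.5 and 31.7 fragments. The absolute depth of the Huh7 libraries is unknown, since human transcript lengths were not used here. Whole counts were not recovered for every gene, so no count test was run. AMLN gene coordinates were checked against RefSeq on GRCm38: 84.7% of gene starts were equal, so the table counts from 1.

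Before the data were examined, the design assumed read counts and named a branch for FPKM, which was used throughout. For the mouse tables no test was made and no p-value was computed, since each group holds 1 library. Genes with an FPKM of at least 1 in 1 of the 2 libraries, a minimum the design gave only for the choice of named genes, were compared by the difference of log2(FPKM + 1), and a gene was counted when that difference was at least 1 in size. In the text, at least 2-fold means a difference of at least 1 on this scale, in the Huh7 numbers too. This scale understates the change of genes with low values. In counts from the authors' deposited tables, at least 2-fold instead refers to the authors' log2 fold change, with no FPKM minimum. Fold values are ratios of the FPKM themselves. A total of 35 mouse gene lists and 20 human lists were fixed before the data were examined. They cover pathways, liver and immune cell types, other tissues and genes near Gpnmb. In each mouse table, the median of every list with at least 4 measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was counted as outside when it lay beyond the central 95% of these.

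For Huh7, limma-trend was run on log2(FPKM + 1) with treatment and replicate number, the number acting as a block because the submitters' tables compare the treatments within each number. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The design named no filter for FPKM. The filter used, an FPKM of at least 1 in 2 libraries, was chosen after the files had been opened. With 4 libraries and the block, 1 residual degree of freedom was left. In the main fit the estimated prior degrees of freedom were infinite, so every gene received the spread of the trend line and its own spread was not used. Same-numbered libraries deviated together from their treatment means (r = 0.947 across genes), and the first principal component, with 77.1% of the variance, separated the numbers. Nothing in the labels says that the libraries of 1 group are separate cultures. The p-values rest on how closely the treatment differences of the 2 numbers match, pooled over genes of like expression. They do not measure the spread between libraries of 1 group, which the block takes up. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Both compare a list with other genes. They were also tested with fry, which compares a list with no change after the median of each library was subtracted. GC content and transcript length came from mouse transcripts of the same gene name, which covered 89.0% of the tested genes. The GC correction fitted a natural spline per library and was followed by a blocked fit of the same design, with its prior estimated anew.

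The Huh7 fit was tested on simulated data for 11123 genes with 200 changed genes, in 2 versions. The first drew each gene's spread from the residual SDs of the real genes and found 0% of the changed genes at log2 changes of 0.25, 0.5 and 1. After that result a second version drew the spread from the fitted trend, which is the assumption the fit itself makes. It found 25.5% of the changed genes at 0.25, 98.5% at 0.5 and 100% at 1, with 16.4%, 7.51% and 7.41% false among the calls. Which of these spreads is right for the real libraries was not shown, and the second is the favourable one. The list method was tested on 100 simulated lists of 15 members per mouse table: lists shifted by 1 were found 100 times out of 100. Unshifted ones lay outside 3 times for HFHC against ND and 7 times for the knockout comparison.

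The genes named in the text follow a rule fixed before the data were examined. They are Gpnmb and Ryk in each library, the 10 highest and 10 lowest genes of each mouse table, the 10 largest changes in each direction among passing Huh7 genes with the same sign in both numbers, and up to 4 members of each list. Genes named outside this rule were chosen after their values were seen, and the text says so. A few genes that the rule names are not reported here. Alternatives were another pseudocount (0.1), no filter, an FPKM minimum of 5, centring (the median log2 ratio subtracted for mouse tables and Huh7 pairs, the median of each library for the Huh7 fit and GC analysis), a fit with no replicate block, leaving out each Huh7 library and the GC correction. Genes with near-identical copies (Mup, Saa and Serpina1 families, histones, metallothioneins, U2AF1) and readthrough genes are uncertain, since how shared reads were assigned is not given in the sources used here. Tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.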

Results

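The series profiled mouse liver on steatohepatitis diets, liver without Gpnmb, and human hepatoma cells exposed to the extracellular domain of GPNMB, a membrane glycoprotein of macrophages and other cells. The tables list 17503 genes for HFHC and ND, 16000 for the AMLN livers and 17681 for Huh7. Genes with an FPKM of at least 1 numbered 11109 in HFHC, 9846 in ND, 9424 in the AMLN knockout and 9673 in the AMLN wild type. They numbered 10824 and 10848 in the vehicle libraries of Huh7 and 10908 and 10870 in the ECD libraries. Each mouse group is 1 liver library, so the mouse differences have no replicate check and carry no p-value.

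Gpnmb itself differed strongly between the livers. On GRCm38 it lies on chromosome 6 from 49036518 to 49058182, and Ryk on chromosome 9 from 102834920 to 102908307. Gpnmb stood at 120.53 FPKM in HFHC and 0.22 in ND, a 548-fold ratio and a log2 difference of 6.64. On the AMLN diet it stood at 2.13 FPKM in the wild type and was listed at 0 in the knockout. The target gene thus matches the genotype labels. The wild-type value stands for an estimated 135.0 fragments, read from the authors' deposited p-value. Ryk differed little, with 15.92 FPKM in HFHC and 15 in ND, and 14.1 in the knockout and 10.79 in its wild type. In Huh7, GPNMB (GRCh38 chromosome 7, 23246766 to 23278217) was low in each library, at 2.21 and 2.04 FPKM with vehicle and 1.48 and 2.04 with ECD. RYK (chromosome 3, 134152642 to 134251313) stood at 669.77 and 838.96 FPKM in the vehicle and ECD libraries of number 1. It stood at only 43.41 and 45.14 in those of number 2.

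**Figure D1:**
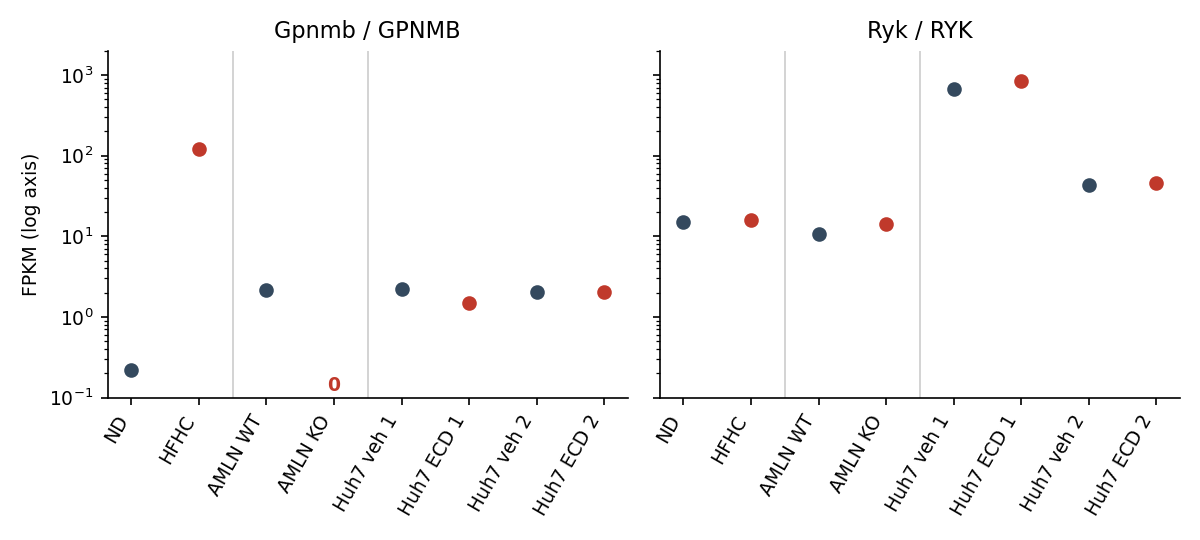
FPKM of Gpnmb or GPNMB (left) and Ryk or RYK (right) in each of the 8 libraries, on a log axis; dark points are ND, wild type or vehicle, red points HFHC, knockout or ECD, and a red 0 marks a gene listed at 0. Gpnmb stands at 120.53 in HFHC against 0.22 in ND, and RYK differs between Huh7 numbers 1 and 2.

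The first comparison asked what the HFHC diet was associated with in wild-type liver. The HFHC library was higher in macrophage, antigen presentation, inflammatory and matrix genes. It was lower in genes of cholesterol synthesis, fatty acid oxidation and PPAR-alpha targets, and cytochrome P450. Of 11178 genes compared, 1213 were at least 2-fold higher in HFHC and 117 lower. The macrophage genes Mmp12, a matrix metalloprotease (62.36 against 0.42 FPKM, log2 5.48), Trem2, a lipid-sensing receptor (51.59 against 0.97, 4.74), and Lgals3, galectin-3 (138.64 against 2.55, 5.30), were among the 10 highest after Gpnmb. The acute phase genes Saa2 (853.06 against 10.46, 6.22), Saa1 (1293.38 against 34.17), Saa3 (260.74 against 6.1) and Orm2 (4.38) and the iron-binding Lcn2 (788.37 against 10.87, 6.06) belonged there too, as did Ptgds, a prostaglandin D synthase (4.30). The lowest was Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis (29.87 against 905.44, −4.88). It was followed by Car3, a carbonic anhydrase (−4.42), the urinary protein genes Mup12 (−4.27), Mup1 (−3.57), Mup18 (−3.16), Mup13 (−3.09) and Mup9 (−2.91), Ugt1a5 (−3.30), the acyl-CoA thioesterase Acot3 (−3.18) and Hamp, which encodes the iron hormone hepcidin (−2.78).

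All 15 measured members of the lipid-associated macrophage list were at least 2-fold higher in HFHC, with a median log2 difference of 3.55 that includes Lpl, lipoprotein lipase (4.30). The Kupffer cell list had 8 of 10 members at least 2-fold higher (median 1.97), among them Cd5l (3.51) and the complement genes C1qb (3.40), C1qc (3.02) and C1qa (2.77). The other 2 members were not higher at all, though not 2-fold lower. All 9 monocyte genes were higher (median 2.08), including lysozyme Lyz2 (4.09) and Cd14 (3.04), as were all 6 neutrophil genes (median 1.79), including S100a8 (2.48). MHC class II genes had 6 of 7 members at least 2-fold higher (median 3.43), with H2-Aa at 3.66 and the invariant chain Cd74 at 3.56. In the T and NK cell list 6 of 7 were higher (median 1.10), with Cd3g at 1.75, though with a pseudocount of 0.1 this list lay inside. The B and plasma cell list stayed inside the range of matched random lists, with a median of 0.65. The lysosome list had 7 of 21 members higher (median 0.78), with cathepsins Ctss (3.93) and Ctsk (1.97).

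Inflammatory and acute phase genes were at least 2-fold higher in 17 of 21 cases (median 1.74). Matrix genes were higher in 21 of 27 (median 1.47), with the protease inhibitor Timp1 (15.84 against 0.12 FPKM, 3.91) and the collagen genes Col1a1 (3.45), Col1a2 (2.97) and Col3a1 (2.87). The cholangiocyte list was higher (5 of 6, median 1.24), with osteopontin Spp1 (2.44) and keratin Krt19 (1.57). Immediate early genes (10 of 17), including Klf6 (2.31) and Egr1 (1.65), interferon-stimulated genes (4 of 12, 0.76, inside at an FPKM of at least 5), including Oasl2 (1.76), and NRF2 targets (4 of 11, 0.65), including heme oxygenase Hmox1 (1.80), also lay above matched random lists. Red blood cell genes moved with them (2 of 5, 0.74), with Hba-a1 at 1.15.

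Cholesterol synthesis and LDL uptake genes were at least 2-fold lower in HFHC in 11 of 23 cases (median −0.83), including Tm7sf2 (−2.19), Idi1 (−2.10), Cyp51 (−1.62) and squalene epoxidase Sqle (−1.53). The list of fatty acid oxidation genes and PPAR-alpha targets was lower in 3 of 22 (median −0.72), with the kinase Pdk4 at −1.88 and Acot1 at −1.50. Xenobiotic cytochrome P450 genes (2 of 9, median −0.45), including Cyp2c29 (−1.73), and bile acid genes (3 of 15, median −0.25) also lay below random lists. The bile acid list went both ways: Cyp7a1, the rate-limiting enzyme, stood at −2.52, and Nr0b2, which encodes the repressor SHP, at 1.90. Pericentral hepatocyte genes (median −0.11) and WNT ligands and receptors (0.18) lay just below their random lists, the latter inside with a pseudocount of 0.1 or an FPKM of at least 5. Lists inside that range were fatty acid synthesis (0.22, with Lpin1 at 2.54 and Me1 at −1.56), lipid droplet genes (−0.01, with G0s2 at −2.53), sinusoidal endothelial cells (0.13), hepatocyte identity (0.07), periportal hepatocytes (−0.05), the unfolded protein response (0.12, with Atf3 at 2.59), cell cycle (0.54), circadian clock (0.18), WNT targets (0.23), glycolysis and hypoxia (0.49, with Pkm at 2.21) and neighbours of Gpnmb (0.24). In all, 20 of 32 lists lay outside the range, 14 higher and 6 lower. Adipocyte, exocrine pancreas and skeletal muscle genes had under 4 measured members, the most different being Mylpf, a muscle myosin light chain (2.25 against 0.41 FPKM).

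The median gene was 0.30 higher in HFHC on the log2 scale, so differences are also given relative to it: Gpnmb then stood at 6.34. Subtracting that median changed the split from 91.2% higher among 1330 genes to 73.3% higher among 926 (679 higher, 247 lower). The authors' deposited table holds 3519 genes at least 2-fold higher in HFHC and 209 lower at a false discovery rate of 0.05. These counts use the authors' log2 fold change with no FPKM minimum and compare 2 libraries.

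The second comparison asked what loss of Gpnmb was associated with on the AMLN diet. Genes of lipid droplets, fatty acid synthesis, MHC class II, matrix and inflammation were lower in the knockout library, and genes such as Igfbp1 and G6pc were higher. Of 9843 genes compared, 53 were at least 2-fold higher in the knockout and 132 lower, with a median difference of −0.05. The lowest genes were Cidea (0.24 against 24.74 FPKM, −4.38) and Cidec (4.68 against 66.29, −3.57), which encode proteins that enlarge lipid droplets. Cd36, a fatty acid transporter (5.38 against 43.42, −2.80), Mogat1, a monoacylglycerol acyltransferase (−2.64), Apoa4, an apolipoprotein (−2.43), Lgals1, galectin-1 (−2.49), Mup17 (−3.18), Mup9 (−2.64) and Fmr1nb (−2.38) were also among the 10 lowest. Entpd4 was listed at 0 in the knockout and at 7.52 FPKM in the wild type.

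Among the 10 highest were Serpina1e, a member of the alpha-1 antitrypsin family (8439.8 against 553.42 FPKM, 3.93), Enho, which encodes the peptide adropin (3.34), and Igfbp1, an insulin-repressed binding protein (224.4 against 27.24, 3.00). Selenbp2 (2.92), Gadd45g (2.53), the glycogen phosphatase subunit Ppp1r3g (2.34), Foxq1 (1.95), Hsd3b5 (1.81) and G6pc, the glucose-6-phosphatase of gluconeogenesis (303.87 against 94.09, 1.68), were higher too. Adipoq, an adipocyte hormone, was listed at 0 in the wild type and at 2.68 FPKM in the knockout, and Retn of the same adipocyte list was higher (2.91 against 0.34, 1.54), while Cfd was lower (30.35 against 92.91, −1.58). The muscle genes Acta1, Tnnc2 and Tnnt3 were listed at 0 in the wild type and at 1.32, 1.14 and 1.02 FPKM in the knockout. The skeletal muscle list (3 of 4 higher, median 1.06) thus lay above random lists, and the exocrine pancreas gene Cela1 stood at 15.29 against 7.58 FPKM. These muscle and pancreas traces, and 2 of 3 adipocyte genes, stood higher in the knockout library beside the lower lipid genes.

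The lipid droplet and fatty acid uptake list had 8 of 16 members at least 2-fold lower in the knockout (median −0.91). Fatty acid synthesis genes were lower in 6 of 19 cases (median −0.58), with the elongase Elovl5 (−1.62), the desaturase Scd1 (2329.14 against 5749.47 FPKM, −1.30) and fatty acid synthase Fasn (−1.22). Cholesterol synthesis genes were lower in 2 of 23 (median −0.44), namely Fdps and Hmgcs1. The list of fatty acid oxidation genes and PPAR-alpha targets was lower in 3 of 22 (median −0.22), with Vnn1 at −1.94 and the hormone gene Fgf21 at −1.08. NRF2 targets (median −0.55), with Gsta1 at −2.09, and xenobiotic cytochrome P450 genes (−0.39), with Cyp2b10 at −1.89, also lay below random lists, the latter inside at an FPKM of at least 5.

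MHC class II genes (2 of 6 lower, median −0.96) included H2-Eb1 (−1.16) and H2-Ab1 (−1.01). Matrix genes (4 of 19 lower, −0.51) included Col3a1 (−1.25), Dpt (−1.19), Sparc (−1.10) and Col1a1 (−1.05). Inflammatory and acute phase genes (4 of 14 lower, −0.54) included Saa2 (−2.07), Lcn2 (−2.04) and Saa1 (−1.23). The lipid-associated macrophage list had 3 of 13 members lower (−0.33), namely Mmp12 (−1.76), Lgals3 (−1.34) and Trem2 (−1.12), while Fabp5 stood at 0.94. Sinusoidal endothelial genes (median −0.72), with Cdh5 at −0.79 and Pecam1 at −0.76, and Kupffer cell genes (−0.33), with Cd5l at −0.73, lay below random lists with no member at a difference of −1 or below. Monocyte genes (−0.17) lay inside, with Lyz2 at −1.04.

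Circadian clock genes (median 0.15), with Nr1d1 at −0.60 and Cry1 at 0.42, and immediate early genes (0.17), with Dusp1 at 1.09 and Dusp6 at −1.18, lay above random lists, the circadian list inside at an FPKM of at least 5. Inside the range were hepatocyte identity (0.16, with Tat, tyrosine aminotransferase, at 1.47), pericentral (−0.19) and periportal (0.11) hepatocytes, bile acid genes (−0.05, with Cyp7b1 at 1.23), interferon-stimulated genes (−0.12), the unfolded protein response (0.01, with Asns at 1.01), lysosome (−0.15), cell cycle (0.04), glycolysis (−0.08), WNT targets (−0.13, with Myc at 1.05), WNT ligands and receptors (−0.04), red blood cells (−0.12) and neighbours of Gpnmb (−0.13, with Osbpl3 at −1.08). In all, 15 of 29 lists lay outside, 3 higher and 12 lower. The T and NK, B, neutrophil, cholangiocyte and adipocyte lists had under 4 measured members. Subtracting the median gave 61 genes higher and 104 lower. The authors' deposited table holds 148 genes at least 2-fold higher and 480 lower at a false discovery rate of 0.05. These counts too use the authors' log2 fold change with no FPKM minimum.

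**Figure D2:**
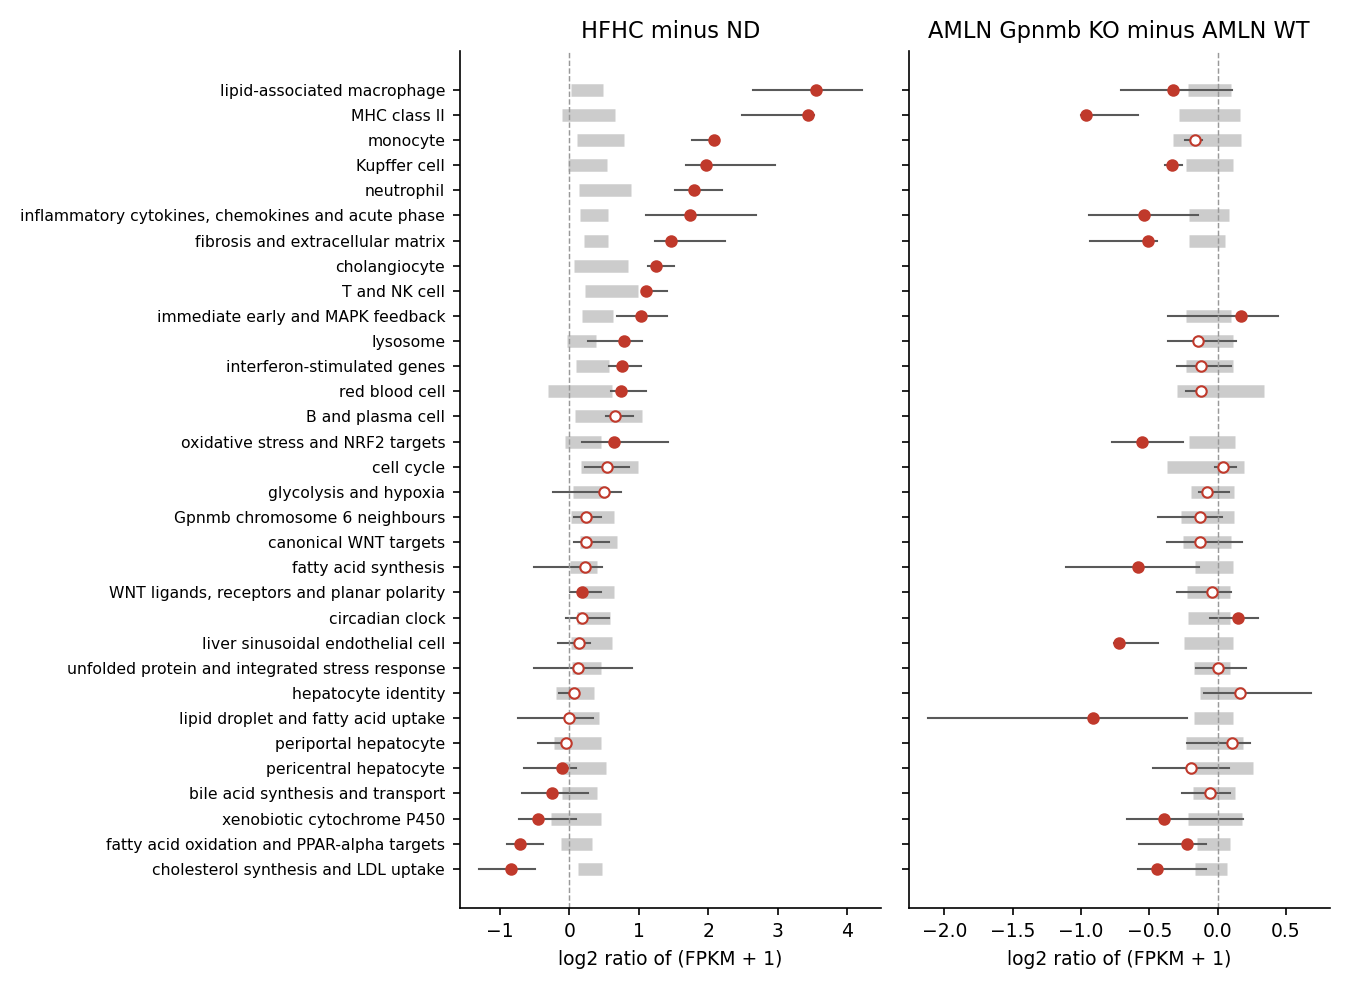
Median log2 ratio of (FPKM + 1) of each gene list, for HFHC minus ND (left) and knockout minus wild type on AMLN (right); thin lines span the quartiles of members and grey bars the central 95% of matched random lists, with filled points outside the bar. The lipid-associated macrophage median is 3.55 on the left and −0.33 on the right.

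The third comparison asked whether genes that differed with HFHC differed the other way in the knockout. Across 9691 genes other than Gpnmb the log2 differences were not related (Spearman rho 0.00651), a correlation across genes, which are not independent replicates. Among genes at least 2-fold different in both, 36 were higher in HFHC and lower in the knockout, where independent lists would share 10.7. These included Saa2, Lcn2, Mmp12, Lgals3, Trem2, Col1a1, H2-Ab1 and Scd1. The reverse held for 7 genes, where 0.472 would be shared, including Serpina1e, G6pc and Cyp7b1. The same direction held for 25 genes, where 4.98 would be shared, including Cidea, G0s2, Me1, Fdps and Hmgcs1, which were lower in both. Diet and months differed between the tables, and each effect is a difference of 2 libraries.

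The fourth comparison asked what GPNMB ECD changed in Huh7 cells with RYK over 8 hours. Changes were small and went the same way in both numbers for most genes. Of 11123 genes, 7052 passed limma's adjusted p of 0.05, 4598 higher and 2454 lower with ECD, around a median log2 change of 0.14. Among 10675 genes with an FPKM of at least 1 in 1 library of each number, only 4 were at least 2-fold different in both on the log2(FPKM + 1) scale, where independent lists would share 0.0334: U2AF1 was higher, and COMMD3-BMI1, NKIRAS1 and LOC101927345, named after its values were seen, were lower. At 1.5-fold in both numbers, 7 genes were higher and 263 lower, so without a GC correction the larger changes were mostly falls. This count was not made after the GC correction described below. At 2-fold after it, 1 of 9899 genes was higher and 43 were lower in number 1, and 2 and 1 in number 2. The log2 ratios of the numbers correlated across these 10675 genes (Spearman rho 0.802).

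The largest rise was that of U2AF1, a splicing factor gene with a near-identical copy, at a log2 change of 1.65 ± 0.0991 (SE, n = 2 per group, limma's adjusted p = 1.66e-57). It went from 0.1 to 2.76 FPKM in number 1 and from 2.56 to 9.2 in number 2, so its lowest value lies near the floor. The metallothionein genes MT1E (0.96 ± 0.0846) and MT1X (0.89 ± 0.0871), which bind metals, rose, as did galectin-1 LGALS1 (0.71 ± 0.0856), the histone genes H4C12 (1.19 to 3.76 FPKM in number 1 and 0.45 to 1.67 in number 2) and H2BC6 (0.68), TSTD3 (0.72) and MTRNR2L9 (0.66). The readthrough genes FMC1-LUC7L2 (0.78) and ANKHD1-EIF4EBP3 (0.69) were in this group too. The largest fall was that of COMMD3-BMI1, a readthrough gene, at −1.43 ± 0.0817 (adjusted p = 2.34e-63). NKIRAS1, an inhibitor of NF-kappa-B signalling, fell from 83.96 to 31.25 FPKM in number 1 and from 61.38 to 29.94 in number 2 (−1.20 ± 0.0816). BCAT1, a branched-chain amino acid transaminase (−1.07 ± 0.0815), SRP9, a signal recognition particle subunit (−1.05), SCOC (−1.12), GOLT1B (−1.05), PHOSPHO2 (−1.06), ZNF92 (−1.06), ASDURF (−1.07) and POC1B-GALNT4 (−1.23) also fell. Some of these changes were much larger in 1 number than in the other. For ASDURF the change was −1.79 in number 1 and −0.35 in number 2. In the same order it was 1.22 and 0.09 for MTRNR2L9, 1.24 and 0.32 for FMC1-LUC7L2, and 0.33 and 1.034 for H2BC6. The log2 changes of the other genes in this paragraph differed less between the numbers. The fit did not use a gene's own spread, so the calls do not weigh such gaps gene by gene.

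Where a gene named below lost its call with the GC correction, its log2 change after it is given as corrected. CYP51A1, SLCO1B1, SLCO1B3 and CYP2B6 have no GC value, so the correction was not run on them. The same holds for many genes with the largest changes above. These are COMMD3-BMI1, POC1B-GALNT4, ZNF92, LOC101927345, MT1E, MT1X, H4C12, H2BC6, MTRNR2L9, FMC1-LUC7L2 and ANKHD1-EIF4EBP3. Genes that kept their call moved in size too, some to smaller changes and others to larger ones, such as LRP6 (−0.60) and G0S2 (−0.55). Rises and falls in the list counts that follow are calls against no change. Over all 11123 genes 4598 rose and 2454 fell, so 65.2% of all calls were rises, around a median log2 change of 0.14. In the cholesterol synthesis list 15 of 24 members rose and 7 fell, the largest changes being falls of STARD4 (−0.74 ± 0.0819), SC5D (−0.50), CYP51A1 (−0.43) and MSMO1 (−0.40). Fatty acid synthesis genes rose in 8 of 19 cases and fell in 2: FASN stood at 0.35 (corrected 0.09), SREBF1 at 0.33 (corrected 0.07), ELOVL5 at −0.52 and GPAM at −0.35. In the unfolded protein list 14 of 19 rose and 1 fell, DNAJB9, a chaperone gene (−0.87 ± 0.0819), while DDIT3 rose by 0.33 (corrected 0.10). Lysosomal genes rose in 13 of 19 cases, with CTSD at 0.31 (corrected 0.09), and fell in 2, with LAMP2 at −0.42 (corrected −0.07). NRF2 targets rose in 5 of 11 and fell in 3, with SLC7A11 at −0.69. Hepatocyte identity genes rose in 10 of 15 and fell in 1, with APOA1 at 0.29 (corrected 0.07). Cell cycle genes rose in 7 of 16 and fell in 5, with CCNE2 at −0.61 (corrected −0.10) and AURKB at 0.36. Immediate early genes rose in 10 of 16 and fell in 3, with JUNB at 0.35 (corrected 0.08) and the phosphatase DUSP6 at −0.40. WNT ligands and receptors rose in 5 of 12 and fell in 2, with the coreceptor LRP6 at −0.44 and DVL1 at 0.35 (corrected 0.08). WNT targets rose in 1 of 10, MYC (0.31, corrected 0.08), and fell in 1, DKK1 (−0.26, corrected −0.11).

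Matrix genes rose in 6 of 13 and fell in 1, LOX (−0.69, and −0.42 after the GC correction with its call kept). Inflammatory genes rose in 5 of 10, with NFKBIA at 0.36, and fell in 1, CXCL2 (−0.51). Both kept their call after the GC correction, at 0.20 and −0.26. Fatty acid oxidation and PPAR-alpha target genes rose in 9 of 16 and fell in 2, ACADM (−0.54) and EHHADH (−0.44). Glycolysis and hypoxia genes rose in 7 of 17 and fell in 1, PDK1 (−0.33, corrected −0.20). Macrophage-list genes rose in 4 of 7, with CAPG at 0.39 (corrected 0.14), and lipid droplet genes rose in 2 of 8 and fell in 1, G0S2 (−0.31). Bile acid genes rose in 2 of 9 and fell in 2, SLCO1B1 (−0.67) and SLCO1B3 (−0.58). Circadian genes rose in 3 of 13 and fell in 3, with NR1D2 at −0.55. The xenobiotic cytochrome P450 and interferon lists had under 5 measured members, with CYP2B6 at 0.30. RYK stood at 0.19 (adjusted p = 0.0443) and GPNMB at −0.19 (adjusted p = 0.0976). Adjusted over the list alone, the cholesterol list held 22 calls, the unfolded protein list 15, the lysosome list 15 and the immediate early list 14. No list stood apart from other genes by camera, where 0 of 18 passed with the preset or the estimated correlation (lowest adjusted p = 0.761 and 0.963). The estimated correlation rests on 1 residual degree of freedom, so a list could hardly pass there and that result adds little. By fry, which tests a list against no change after the median of each library was subtracted, the lowest adjusted p was 0.0967.

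Log2 ratios followed the GC content of the matching mouse transcripts, with a Spearman rho of 0.644 in number 1 and 0.656 in number 2 across genes. After a GC correction 2789 of 9899 genes passed, 1384 higher and 1405 lower, against 6434 before it. Limma called 0 genes without the replicate block (651 at an unadjusted p of 0.05, where chance gives 556), and 0 with no filter on low values (6558 unadjusted), a filter chosen after the files had been opened. The fits that left out 1 library also dropped the block, so they cannot show what a single library contributes to the calls.

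**Figure D3:**
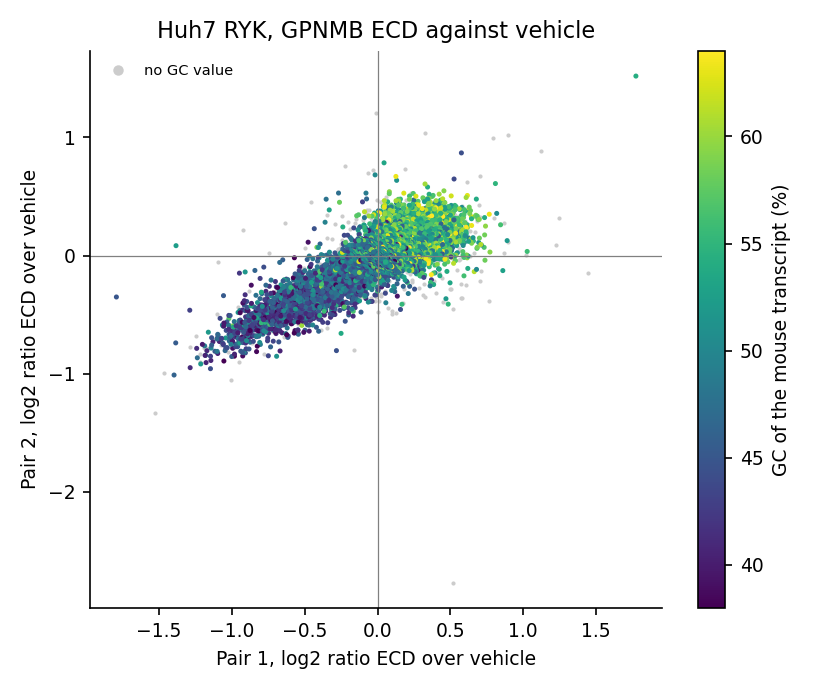
Log2 ratio of ECD over vehicle in number 1 (x axis) and number 2 (y axis), 1 point per gene, coloured by the GC content of the mouse transcript of the same name, grey where there is none. The ratios correlate at a Spearman rho of 0.802, and low-GC genes lie at the lower left.

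**Figure D4:**
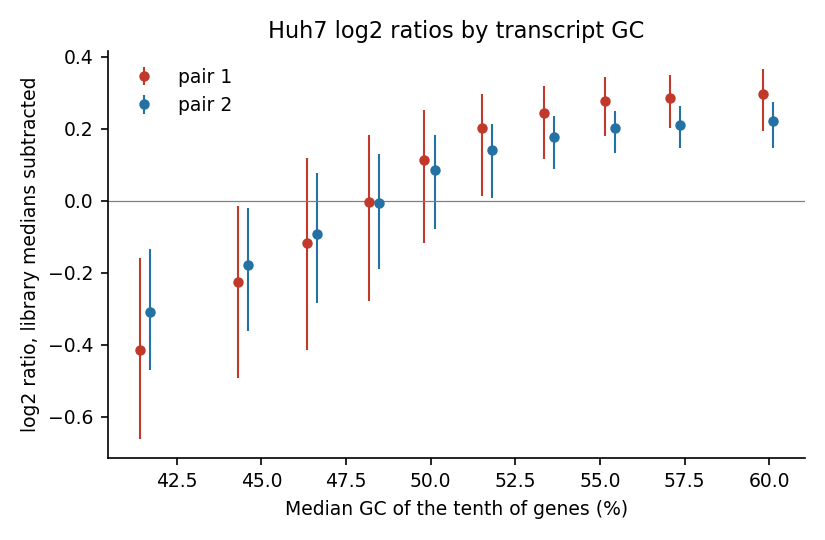
Median log2 ratio of ECD over vehicle, with the median of log2(FPKM + 1) over genes subtracted in each library, in 10 equal groups of genes by GC content (%), quartiles as bars, numbers 1 (red) and 2 (blue). In number 1 the median goes from −0.42 in the lowest group to 0.30 in the highest, and in number 2 from −0.31 to 0.22.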

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

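The comparison of the authors' fold changes with the FPKM ratios was chosen after the values had been seen. In the authors' deposited Huh7 tables, the log2 fold change lies above the log2 ratio of the FPKM columns by a median of 0.226 in number 1 (7972 genes) and 0.0706 in number 2 (8104 genes), which no comparison in the report uses. In the mouse tables the median offset is 0. The log2 of the relative depth of ECD over vehicle is 0.22 in number 1 and 0.07 in number 2, near the Huh7 offsets. It was read from the authors' p-values for genes listed at 0 in 1 library. These p-values were deposited with the fold changes, so the 2 measures may not be independent. The authors' deposited Huh7 tables, whose fold changes carry these offsets, hold 186 genes at least 2-fold higher and 91 lower in number 1, and 67 and 57 in number 2, at a false discovery rate of 0.05. By the difference of log2(FPKM + 1) alone, 7 genes were at least 2-fold higher and 84 lower in number 1, and 3 and 4 in number 2. With a pseudocount of 0.1 instead, these were 23 and 154, and 11 and 9. The authors' counts also differ in FPKM minimum and false discovery rate, so the offsets alone cannot be read as the cause of the gap.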

How the results depend on the processing

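The centring, FPKM minimum of 5 and all alternatives of the diet against knockout comparison, and the other pseudocount for mouse lists and Huh7 pairs, were chosen after seeing the data, as was the Huh7 filter itself; the GC correction was added after the files were opened but before its result was seen. Alternatives fixed beforehand that need counts were not run: TMM, library totals, DESeq2 size factors and Wald test, count minimums, prior counts and filterByExpr. The cause of the changes below was not tested unless stated.

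Genes at least 2-fold different numbered 2105 for HFHC against ND with a pseudocount of 0.1 and 817 at an FPKM of at least 5, where fewer genes enter. The knockout comparison gave 371 with a pseudocount of 0.1. The diet against knockout rho was 0.0856 at an FPKM of at least 5 and −0.0178 with a pseudocount of 0.1, where opposite directions held for 111 genes and the same direction for 57. Mouse lists outside random lists ranged from 16 to 20 for HFHC and 12 to 15 for the knockout. T and NK, WNT receptor and interferon lists (HFHC) and cytochrome P450 and circadian lists (knockout) returned inside under 1 alternative or more, and the HFHC circadian list went below at an FPKM of at least 5. No named mouse gene at least 2-fold different turned; Ryk in HFHC against ND, at 0.08, went to −0.22 after centring.

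In Huh7, limma called 0 genes with no replicate block, centred or not (651 and 693 at an unadjusted p of 0.05), so the calls rest on pairing libraries by a number whose meaning is not given. The GC correction gave 2789 calls, 2117 of them among the 7052. No filter on low values gave 0, a pseudocount of 0.1 gave 7038, and an FPKM of at least 5 gave 6160. Of 96 named genes, 96 kept direction and call with a pseudocount of 0.1 and 94 after centring each library. That centring only took the median log2 change from 0.14 to 0.12, so it hardly tests calls against the median gene. Genes at least 2-fold different in both numbers were 8 with a pseudocount of 0.1, 2 at an FPKM of at least 5, 11 after centring and 270 at 1.5-fold, where 21.9 would be shared by chance. No list passed under any alternative run, though with the estimated correlation hardly any could. Of 79 named genes with a GC value, 39 lost their call with the GC correction in the same direction and 3 others that had passed turned: PNPLA2 (−0.0311), CEBPA (−0.00195) and DVL3 (−0.00242). CIDEC (−0.0342) and RNF43 (−0.0754), which had not passed, turned too.

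Leaving out 1 Huh7 library, without the block, gave 0 to 0 calls by limma (64 to 398 unadjusted), the lone library being assumed to vary like the others. The difference between numbers then enters the treatment contrast, and 21 of 96 named genes, all of which had passed, turned. Their log2 changes ranged from −1.71 to 3.07 for H2BC6, −1.90 to 2.28 for RYK, −0.00376 to 0.71 for FASN, −0.0663 to 0.73 for ACOT1, −1.51 to 0.18 for SLCO1B1, −0.20 to 0.79 for NR0B2, −0.73 to 1.55 for TIMP1, −0.41 to 1.19 for CAPG, −0.11 to 0.85 for CD68, −1.13 to 1.69 for LGALS3, −1.03 to 0.0159 for CXCL2, −0.15 to 0.87 for NFKBIA, −0.74 to 1.21 for CXCL8, −0.53 to 1.11 for APOA1, −0.23 to 0.76 for CEBPA, −0.0673 to 0.60 for SERPINA1, −0.0417 to 0.73 for SESN2, −0.19 to 0.57 for USP18, −1.20 to 0.68 for DKK1, −0.47 to 1.16 for JUNB and −0.30 to 1.11 for HK1. CYP1A1 (−0.52 to 0.74), CYP3A7 (−0.39 to 0.44) and CCND1 (−0.11 to 0.43), which had not passed, also crossed 0. Large changes that kept their sign moved too: U2AF1 from 0.80 to 2.49, MT1X from 0.24 to 1.55, LGALS1 from 0.11 to 1.30 and COMMD3-BMI1 from −1.84 to −1.01. Depth limits low genes most: a 2 kb mouse gene at an FPKM of 1 rests on about 31.7 to 47.2 fragments.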

Other observations

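The tests of RYK dose, fasting, other liver cells, abundant genes and hepatocyte share, and the comparison of Huh7 numbers, were chosen after the results had been seen; those of GC content, transcript length and genes near Gpnmb were fixed after the files were opened but before their results were seen. What would decide the tests of fasting, other liver cells and abundant genes was rewritten once their values were known.

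The Huh7 libraries numbered 1 and 2 differed from each other more than ECD and vehicle did (SD of log2 ratios 0.577 between numbers, against 0.361 and 0.260 between treatments). In both treatments 398 genes were at least 2-fold higher and 219 lower in number 1. RYK was higher in number 1 (log2 3.92 with vehicle and 4.19 with ECD). Of 13 matrix genes 3 were at least 2-fold higher in both treatments, among them VIM, vimentin (918.03 against 182.81 FPKM with vehicle), and TIMP1 (6.18 against 0.48), and 1 was lower, COL6A1 (0.5 against 3.81). The chemokine gene CXCL8 (50.64 against 15.18) was higher as well. Of 15 hepatocyte identity genes 3 were lower: TTR, transthyretin (91.61 against 466.43), APOA1 (396.09 against 1234.23) and AFP, alpha-fetoprotein (1412.87 against 3614.65), while 1, FGA, was higher (128.15 against 62.1). Cholesterol synthesis genes had a median of −0.49 with vehicle and −0.46 with ECD, hepatocyte identity genes −0.56 and −0.52, and matrix genes 0.57 and 0.74, all number 1 minus number 2. What the numbers stand for is not given in the labels, and these differences were not tested.

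The shared direction of most Huh7 genes in both numbers may be, in part, a GC bias between libraries. The calls after the GC correction came to 43.3% of those before it, and the log2 ratios rose with GC in both numbers, as this explanation needs. The corrected fit estimated its prior anew. NKIRAS1 had an SE of 0.0816 in the main fit and 0.0814 after the correction, with log2 changes of −1.20 and −1.07. Limma's adjusted p for it went from 2.93e-45 to 0.000213. The fall in calls thus cannot be laid to GC alone. The ratios of the numbers still correlated at 0.735 after the correction, so GC content as measured in mouse transcripts does not account for the whole pattern. Transcript length had a rho of −0.298 in number 1 and −0.250 in number 2, too weak to decide. An ECD effect in proportion to RYK, the hypothesis from the design, would widen the ratios in number 1, and the corrected interquartile range was 1.39 times as wide there, which with 1 comparison cannot be told apart from a difference between cultures.

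The lower lipid, matrix and antigen presentation genes in the knockout liver were set against 3 explanations. Passenger alleles near Gpnmb stay open: 0 of the 14 members at least 2-fold lower lie within 10 Mb of it, but only 0.0953 would be by chance, so the test could hardly find any, and effects on distant genes were not tested. Longer fasting stays open. The upper quartile of the fatty acid oxidation and PPAR-alpha target list is −0.0828, which fasting would not give. Yet Igfbp1, G6pc and Tat were higher and Scd1 and Fasn lower, which fasting would give. A lower share of non-hepatocyte cells is argued against for the lipid droplet list, whose upper quartile lay below the lower quartile of hepatocyte identity genes (difference −0.127), with 8 of 16 members below every Kupffer, monocyte and endothelial gene; for matrix and antigen presentation genes it stays open, since those markers were all lower (highest lower quartile −0.240). Loss of Gpnmb, the difference the design names, cannot be told apart from those left open with 1 liver per group.

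In HFHC liver, a lower share of hepatocytes would raise every other cell type alike, and the lower quartile of the macrophage list exceeded the upper quartile of the sinusoidal endothelial list by 2.34 log2 units, which argues against this as the whole cause. A change in the macrophages themselves, in number or state, stays open. The median rise of all genes may come partly from a few abundant genes: rescaling without the 50 most abundant took it from 0.30 to 0.189, with 1010 genes higher and 152 lower, which does not decide. The diet, the difference the design names, was not separable from the single pair of livers.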
